A study of Mus musculus with 21 samples.

How the data were processed

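RNA of 21 libraries from mouse CD8 T cell cultures was measured by RNA sequencing. Per the labels' protocols, RNA was extracted with Trizol and poly(A)+ libraries were made with a NEBNext Ultra kit. Whether strand was kept is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. The submitters' processing notes name bcl2fastq 2.17, HTSeq, edgeR and the mouse build mm9, with no role or order. The aligner, gene annotation, edgeR normalization method and gene filter are not given in the sources used here. The authors deposited 1 table of RPKM (reads scaled to gene length and library size) on a linear scale, with 1 column per library. All 21 columns were matched to samples by name. Gene symbols were used as the table gives them, and 12867 of them matched a mouse gene name table. No coordinates are given, because no genome of the build mm9 was used here. The 13 mitochondrially encoded genes of a planned list are not in the table, nor are Il2, Tox2, Ndufs5 and several myeloid, NK and erythroid markers.

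Whole read numbers were recovered from the RPKM values for 100% of genes within 0.001 reads, a method that recovered all simulated genes of a test table. They showed that the authors' RPKM divisor was the sum of the reads listed for each library, and gave depths of 5347355 to 25218890 reads. Libraries of a group were compared pairwise, and none of the 21 pairs were identical or within sampling noise (chi-square per gene of 1.52 to 54.6 over genes with 20 or more reads), so each counted as 1 replicate.

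Groups came from the labels: 7 groups with n = 3 in 3 experiments. Values were transformed to log2(RPKM + 1), a pseudocount of 1, and genes with RPKM of 1 or more in at least 3 libraries were kept (12630). All libraries entered 1 limma fit (version 3.58.1 in R 4.3.3) with a mean per group, no replicate block and an empirical Bayes trend, with 14 residual degrees of freedom. Tests were two-sided, and Benjamini-Hochberg adjusted p under 0.05 over all genes tested was called a change. The contrasts were chronic against acute in each experiment, NAC against vehicle in chronic cells, NAC chronic against vehicle acute, and the difference of the OT-I or vehicle chronic effect from the polyclonal one. Gene lists numbered 20, and 19 were measured. They were tested with camera (preset inter-gene correlation 0.01, Benjamini-Hochberg over the lists within a comparison). Tests were repeated with a correlation estimated from the data and with fry, a self-contained test. Cell type markers formed 7 further lists. Beside Cd8a and Cd8b1, the CD8 T cell list held Cd3e, Cd3d, Cd3g, Cd2 and Cd5, which CD4 T cells express too. Apart from the additions named below, the groups, tests, gene lists, markers, alternatives and the rule for named genes were fixed before the data were examined.

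Genes were named by this rule. For the 3 chronic against acute comparisons and NAC against vehicle, up to 2 members per list with the largest absolute log2 change were taken, among those with adjusted p under 0.05, mean RPKM of 1 or more in the higher group and no overlap between the libraries of the groups. By chance 10% of genes do not overlap in 3 against 3. The 6 highest and 6 lowest changes over all genes by the same criteria were added, without predicted genes, clones and small RNAs, and so were 12 genes in every comparison, of which 11 are given here (Pdcd1, Havcr2, Lag3, Tox, Tcf7, Il7r, Ifng, Gzmb, Slc2a1, Nqo1 and Mki67). For the other tests the 4 highest and 4 lowest were taken, with no condition on overlap for differences. Some genes the rule takes are left out, and cell type markers are named by their list.

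Replicate numbers are shared by the groups of an experiment. Deviations from the group means of same-numbered libraries correlated across genes in the polyclonal experiment for all 3 pairs (r of 0.446, 0.629 and 0.168). This is a hint, from the data and not from the labels, that the numbers may pair those libraries. Only 1 of the 3 pairs matched its own number best, and both libraries numbered 2, with the r of 0.629, had raised low genes. Alternatives were a pseudocount of 0.1, no filter, a filter of RPKM 5, libraries rescaled to a common median, only the compared groups in the fit, the replicate block, a 2-fold threshold and leaving out each library in turn. After the data were seen, limma's voom on the recovered reads and a fit without 3 libraries whose low genes lay above those of their groups were added. Counts that leave tumour-enriched or discordant genes out of the main calls, with no new fit, were added too. So were the lists of genes moved in OT-I cells or in both the polyclonal and OT-I experiments, as followed under NAC, and the correlations of the OT-I effect with the vehicle and NAC effects.

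The test was checked on counts simulated from the real libraries, with 200 genes changed by known folds, 50 at each size. In the polyclonal comparison (11609 genes) 42% of genes changed 1.25-fold, 80% changed 1.5-fold, 92% changed 2-fold and 100% changed 4-fold were recovered, with 14 false calls. In the NAC comparison (10917 genes) the shares were 46%, 80%, 88% and 96%, with 3 false calls. For the difference of the OT-I from the polyclonal effect (12137 genes) they were 16%, 56%, 80% and 90%, with 9 false calls, and for that of the vehicle effect (10692 genes) 18%, 66%, 78% and 98%, with 10. Of all calls, the false ones were 8.19% for polyclonal, 1.90% for NAC, and 6.92% and 7.14% for the OT-I and vehicle differences. No list was called where none had been changed. Genes were drawn independently of each other, so this does not test lists whose genes vary together. Each gene had the same spread in all groups, so groups of unequal spread in 1 fit were not tested either. In the real data the estimated correlation was 0.569 for the respiratory chain list. Text and figures used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.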

Results

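Poly(A) RNA was sequenced from cultures that the labels give as mouse CD8 T cells, some with tumour cells, in 21 libraries, which fell into 7 groups with n = 3 each. Cells were taken from spleen and inguinal lymph nodes by negative selection, stimulated through the T cell receptor (TCR) for 48 h, and harvested on day 8. In the acute groups no further stimulus was given, and in the chronic groups it was repeated every 48 h. One experiment used polyclonal C57BL/6 cells and plate-bound anti-CD3 (polyclonal acute and polyclonal chronic). Another used OT-I cells, whose transgenic TCR recognises an ovalbumin peptide, in co-culture with B16-F10 melanoma cells pretreated with interferon-γ, with the peptide (OT-I chronic) or without it (OT-I acute). The remaining experiment used C57BL/6 cells with vehicle (vehicle acute and vehicle chronic) or with 10 mM N-acetylcysteine (NAC), a thiol antioxidant and cysteine precursor, added from 48 h onwards (NAC chronic). Acute cells with NAC were not analysed here.

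Expression was measured as RPKM, and 12630 genes passed the filter and were tested. Reads in genes numbered 5347355 to 15147347 per polyclonal library, 13121180 to 25218890 per OT-I library and 14421378 to 17539278 per library of the vehicle and NAC experiment. The 21 pairs of libraries within groups had Pearson r of 0.985 to 0.999 across genes. They differed by more than sampling noise, with a chi-square of 1.52 to 54.6 per gene. Values are given as mean ± SD of 3 libraries in RPKM. Changes are given as log2 change with its standard error (SE) on the log2(RPKM + 1) scale, which understates the change of low genes. Adjusted p values for genes are from limma, and those for gene lists from limma's camera test. The labels do not say that libraries came from separate cultures or animals. Therefore p-values measure only the spread between these samples, which may be technical.

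The first comparison asked what repeated anti-CD3 stimulation changed in polyclonal cells. The macrophage-attracting chemokine gene Ccl3 rose from 5.92 ± 2.07 to 1648 ± 143 RPKM (log2 change 7.93, SE 0.13, adjusted p = 2.06e-20). The type 2 cytokine gene Il13 rose from 3.79 ± 0.811 to 1127 ± 115 RPKM (log2 change 7.89, SE 0.22). They lost transcripts of the memory-associated transcription factor gene Tcf7, which fell from 48.8 ± 1.71 to 2.59 ± 0.283 RPKM (log2 change -3.80, SE 0.067). RNA of the T-box factor gene Eomes fell from 120.2 ± 2.75 to 7.76 ± 0.430 RPKM (log2 change -3.79, SE 0.040). Cell cycle genes were lower, and genes of the ATF4 and amino acid response were higher. In the same libraries, RNA of the CD8 coreceptor chain Cd8a fell from 101 ± 0.556 to 8.48 ± 0.165 RPKM and that of Cd4 rose from 67.5 ± 2.99 to 312 ± 8.04 RPKM. All 7 tested B cell markers rose as well. Which changes of this comparison, those of gene lists included, come from CD8 T cells is therefore open. In all, 8097 genes changed, 3608 higher and 4489 lower (limma, adjusted p under 0.05), of which 929 rose and 724 fell at least 2-fold. With each library rescaled to the same median, 4092 were higher and 3848 lower.

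Genes induced by the TCR rose as a list in polyclonal chronic cells, with 15 of 20 members higher and 4 lower (camera, adjusted p = 1.18e-05, and adjusted p = 0.0435 with an estimated correlation). Tnfrsf4, which encodes the costimulatory receptor OX40, rose from 22.9 ± 2.05 to 255 ± 9.46 RPKM. Spry1, an inhibitor of Ras signalling, rose from 0.396 ± 0.0368 to 13.96 ± 1.03 RPKM. The list of cytokines, chemokines and cytotoxic molecules had 15 of 20 members higher and 5 lower (adjusted p = 0.000906, but adjusted p = 0.0613 with an estimated correlation). Besides Ccl3, the interleukin 10 gene Il10 rose from 3.43 ± 1.38 to 380.2 ± 15.7 RPKM. Ifng rose from 7.38 ± 0.960 to 118 ± 9.94 RPKM and granzyme B RNA (Gzmb) rose from 2886 ± 22.1 to 4158 ± 359.8 RPKM. The transcription factors of chronic stimulation had 8 of 14 members higher and 4 lower (adjusted p = 0.0168, but adjusted p = 0.0613 with an estimated correlation). Irf4, a factor that follows TCR signal strength in T cells, rose from 24.96 to 145 RPKM, in libraries where B cell markers rose too. In the vehicle experiment Irf4 was at 19.2 RPKM in acute and 36.2 RPKM in chronic cells. Among 15 inhibitory receptors 8 were higher and 5 lower, and the list did not pass (adjusted p = 0.0501, but adjusted p = 0.0424 with a pseudocount of 0.1). Of its members, Lag3 rose from 101 ± 5.42 to 304 ± 17.5 RPKM, Pdcd1, which encodes PD-1, rose from 30.98 ± 2.12 to 52.6 ± 4.64 RPKM. Havcr2, which encodes TIM-3, rose from 70.7 ± 3.98 to 86.4 ± 2.40 RPKM, Cd200 rose from 0.922 to 69.3 RPKM and Btla rose from 2.53 to 67.3 RPKM. Tox, which encodes an HMG-box factor of exhausted cells, was at 1.05 ± 0.509 RPKM in acute and 1.26 ± 0.0368 RPKM in chronic cells (limma, adjusted p = 0.309, but adjusted p = 0.0104 without polyclonal acute library 2).

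The list of ATF4 and amino acid response genes had 22 of 25 members higher and none lower (camera, adjusted p = 1.26e-07, and adjusted p = 0.0435 with an estimated correlation). Among them, Cth, which makes cysteine from cystathionine, rose from 0.888 ± 0.955 to 13.7 ± 0.902 RPKM and the stress-induced factor gene Atf3 rose from 2.19 ± 0.363 to 22.9 ± 1.48 RPKM. Of 19 endoplasmic reticulum stress genes 18 rose and 1 fell (adjusted p = 1.31e-08, but adjusted p = 0.0738 with an estimated correlation). Those that rose included Xbp1, a factor of the unfolded protein response (from 52.7 to 189 RPKM), and the protein disulfide isomerase gene Pdia6 (from 95.1 to 244 RPKM). Cytosolic heat shock genes had 10 of 12 members higher and none lower (adjusted p = 0.000631, and adjusted p = 0.0435 with an estimated correlation). Its most changed members were the near-identical copies Hspa1a (from 0.0862 to 2.28 RPKM) and Hspa1b (from 0.292 to 3.83 RPKM), between which reads may be split wrongly. The p53 target list had 10 of 14 members higher and 3 lower (adjusted p = 0.00134, but adjusted p = 0.0613 with an estimated correlation). Pmaip1, a pro-apoptotic BH3-only gene, went from 14.2 to 88.99 RPKM and the sestrin gene Sesn1 fell from 33.6 to 7.33 RPKM. Sterol and fatty acid synthesis genes had 15 of 23 members higher and 4 lower (adjusted p = 0.00261, but adjusted p = 0.266 with an estimated correlation). Members included the stearoyl-CoA desaturase gene Scd1 (from 32.8 to 82.1 RPKM) and Insig1 (from 44.5 to 97.6 RPKM).

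The cell cycle list fell, with 24 of 29 members lower and 1 higher (camera, adjusted p = 7.12e-07, and adjusted p = 0.0435 with an estimated correlation). The mitotic cyclin gene Ccnb2 fell from 119 ± 5.88 to 38.5 ± 2.49 RPKM and the proliferation marker Mki67 fell from 167 ± 13.8 to 70.9 ± 2.34 RPKM. The memory and self-renewal list did not pass (adjusted p = 0.0716), with 11 of 20 members lower and 6 higher. Its members moved apart: Tcf7 fell, and the follicular homing receptor gene Cxcr5 rose from 1.09 ± 0.274 to 28.1 ± 0.772 RPKM. The interleukin 7 receptor gene Il7r was at 134 ± 2.99 RPKM in acute and 126 ± 4.90 RPKM in chronic cells (limma, adjusted p = 0.189). Lists of metabolism did not pass. These were the respiratory chain and ATP synthase (75 genes, 16 higher and 10 lower, adjusted p = 0.462), the TCA cycle (adjusted p = 0.252), mitochondrial biogenesis and dynamics (adjusted p = 0.877), glycolysis (adjusted p = 0.0663) and hypoxia targets (adjusted p = 0.971). Single members did change, such as the mitochondrial isocitrate dehydrogenase gene Idh2 (from 7.75 to 23.7 RPKM), the hexokinase gene Hk2 (from 12.2 to 29.3 RPKM), the mitophagy kinase gene Pink1 (from 31.2 to 12.8 RPKM) and Pdk1, an inhibitor of pyruvate entry into mitochondria (from 36.5 to 10.5 RPKM). NRF2 and antioxidant genes (adjusted p = 0.572), metallothionein and zinc genes (adjusted p = 0.682) and interferon-stimulated genes (adjusted p = 0.145) did not pass either. Within them Hmox1, a haem oxygenase gene, rose from 5.99 to 15.8 RPKM and the interferon-induced genes Ifit2 (from 23.5 to 3.11 RPKM) and Ifit3 (from 15.6 to 1.13 RPKM) fell. Slc2a1, a glucose transporter gene, rose from 44.3 to 59.04 RPKM, and the NRF2 target Nqo1 was at 2.39 ± 2.00 RPKM in acute and 2.01 ± 0.866 RPKM in chronic cells.

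Genes with the largest rises outside the lists were Ccl22, a chemokine gene (from 1.14 to 938 RPKM), the steroid-metabolising enzyme gene Akr1c18 (from 2.30 to 1297 RPKM). Next came the parathyroid hormone gene Pth (from 1.13 to 724 RPKM) and Mzb1, a chaperone gene of B and plasma cells (from 1.08 to 434 RPKM). The largest falls were in Fam26f (from 41.00 to 0.622 RPKM), Ifit1bl1 (from 39.4 to 0.721 RPKM), Ly6c2 (from 1315 to 62.3 RPKM). Others were the interleukin 18 receptor gene Il18r1 (from 46.02 to 1.54 RPKM), Pydc3 (from 69.5 to 2.84 RPKM) and Lcn4 (from 26.1 to 0.808 RPKM). Ly6c2 and Ifit1bl1 have close copies with which they may share reads.

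Markers of other cells moved together with all of these groups. Cd8b1, the other CD8 chain, fell from 267 ± 7.62 to 23.05 ± 1.55 RPKM, and 4 of 7 genes of the CD8 T cell list fell and 2 rose. Of its members that CD4 T cells express too, Cd3e and Cd3d fell, Cd2 and Cd5 rose and Cd3g did not pass. All 7 tested B cell markers rose, among them Cd79b (from 3.52 ± 1.69 to 114 ± 10.99 RPKM) and Cd79a (from 1.37 ± 0.763 to 50.7 ± 3.59 RPKM). Of the 4 CD4 T cell markers 3 rose, including Cd40lg (from 13.2 ± 1.27 to 43.6 ± 3.89 RPKM). Among myeloid markers Mpeg1 rose, Itgam and Itgax fell and 2 did not pass. The NK cell marker Klrb1c fell from 21.3 ± 0.427 to 0.960 ± 0.444 RPKM and the other 2 NK markers did not pass. Of 12 melanocyte genes Gpnmb rose from 12.5 to 28.1 RPKM and 2 fell. The erythroid marker Alas2 did not pass (limma, adjusted p = 0.193, but adjusted p = 0.00642 with the replicate block). Adjusted over the list alone, the gene list counts were the same except in the respiratory chain (9 higher, 7 lower), NRF2 (8 higher, 10 lower), cell cycle (2 higher, 25 lower), sterol (16 higher, 4 lower) and interferon-stimulated lists (8 higher, 13 lower). The hypoxia list had a positive median and a negative mean, and the NRF2 list the opposite.

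**Figure D1:**
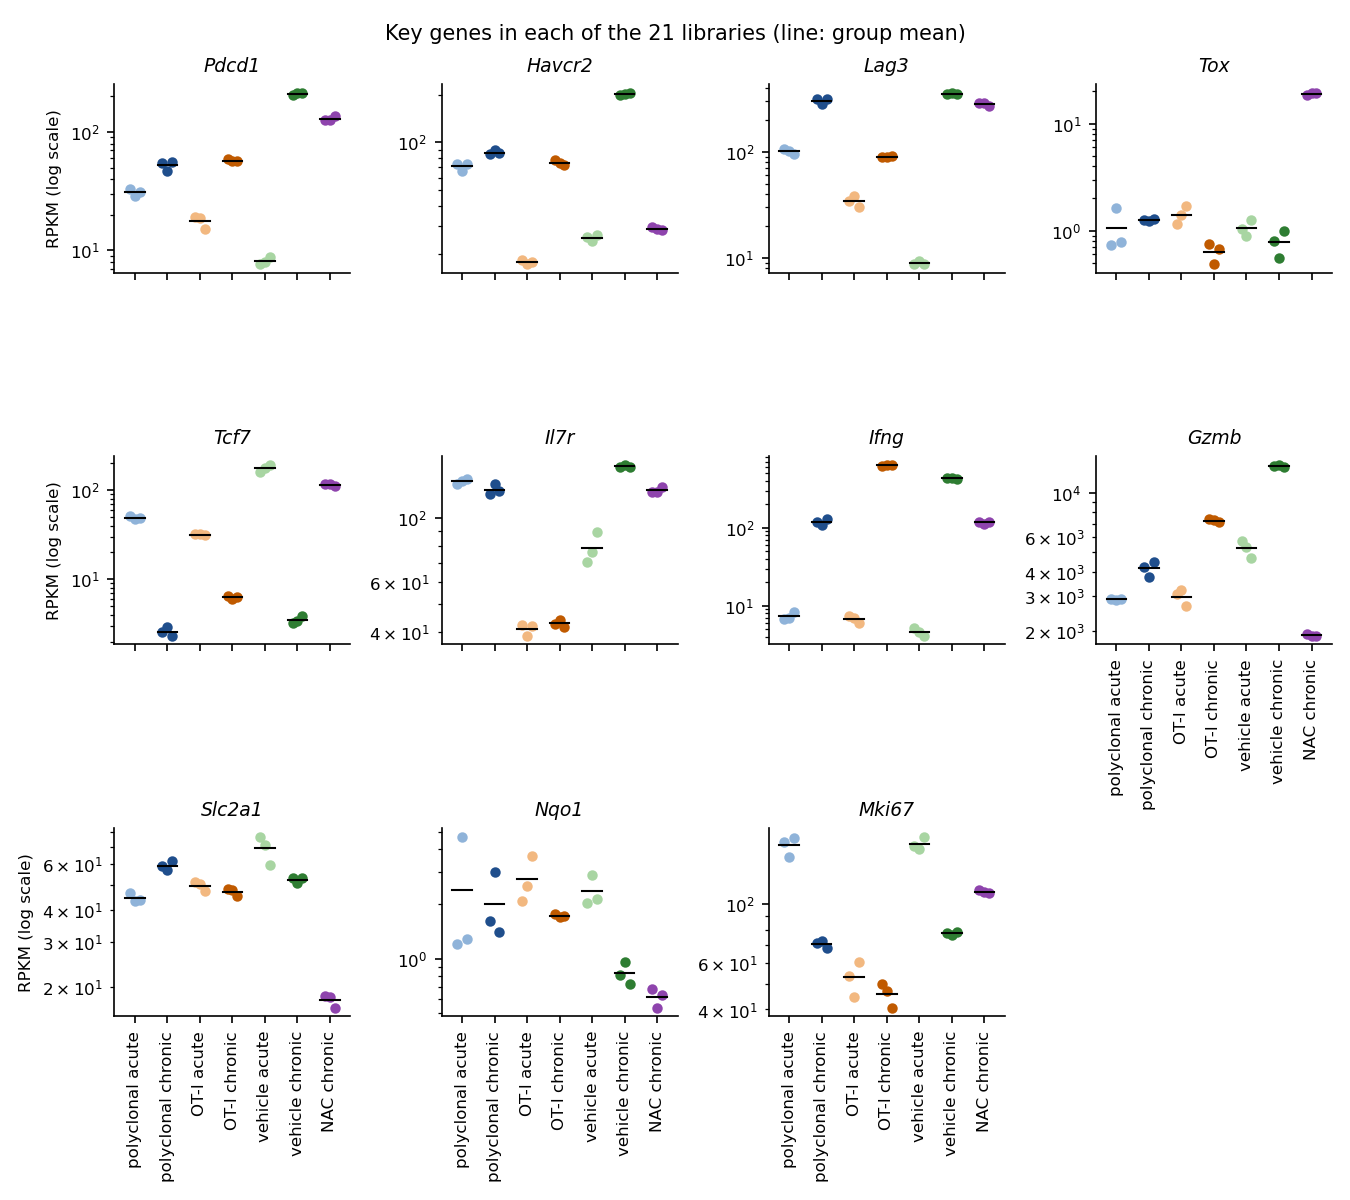
RPKM on a log axis of 11 genes named in advance for every comparison, in each of the 7 groups, with 1 point per library, bars at group means and values under 0.05 RPKM drawn at 0.05. Tcf7 was at 176 ± 17.1 RPKM in vehicle acute, 3.502 ± 0.354 in vehicle chronic and 116 ± 2.58 in NAC chronic libraries.

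The OT-I comparison asked what repeated peptide stimulation changed when OT-I cells were cultured with melanoma cells. Chronic libraries had more RNA of effector molecules, with Ifng rising from 6.82 ± 0.635 to 632 ± 11.9 RPKM (log2 change 6.34, SE 0.079, adjusted p = 8.67e-22). Prf1, which encodes perforin, rose from 25.2 ± 0.847 to 773 ± 18.7 RPKM (log2 change 4.89, SE 0.077). Sterol synthesis genes rose as a block, while the ATF4 response fell. Its target Trib3 fell from 253 ± 21.9 to 40.1 ± 1.22 RPKM (log2 change -2.63, SE 0.081). Tcf7 fell from 31.7 ± 0.543 to 6.28 ± 0.195 RPKM (log2 change -2.17, SE 0.067). These libraries held RNA of the melanoma cells too: the pigment gene Tyrp1 was at 2281 ± 91.98 RPKM in acute and 1244 ± 6.97 RPKM in chronic libraries. Which changes of this comparison, those of gene lists included, come from OT-I cells is therefore open. In all, 7395 genes changed, 2827 higher and 4568 lower (limma, adjusted p under 0.05), of which 368 rose and 352 fell at least 2-fold. With each library rescaled to the same median, the split was 3421 higher and 3609 lower.

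Cytokines, chemokines and cytotoxic molecules had 19 of 20 members higher and 1 lower in OT-I chronic libraries (camera, adjusted p = 6.48e-19, and adjusted p = 0.000286 with an estimated correlation). Gzmb was among them (from 2986 ± 281 to 7259.6 ± 119 RPKM). TCR-induced genes had 17 of 20 members higher and 2 lower (adjusted p = 2.37e-09, and adjusted p = 0.00619 with an estimated correlation). Rgs16, a regulator of G protein signalling, rose from 9.74 to 101 RPKM and the factor gene Irf8 from 16.99 to 69.8 RPKM. The transcription factors of chronic stimulation had 9 of 14 members higher and 4 lower (adjusted p = 0.00262, and adjusted p = 0.0279 with an estimated correlation). Eomes (from 10.2 to 33.9 RPKM) and Nr4a2 (from 3.16 to 8.77 RPKM) were higher. Tox was low and fell from 1.41 ± 0.268 to 0.637 ± 0.137 RPKM. Inhibitory receptors had 8 of 15 members higher and 6 lower (adjusted p = 0.0478, but adjusted p = 0.119 with an estimated correlation). Raised members included Havcr2 (from 17.8 ± 0.569 to 74.7 ± 2.85 RPKM), Pdcd1 (from 17.8 ± 2.19 to 57.3 ± 1.33 RPKM), Lag3 (from 34.3 ± 3.99 to 89.8 ± 0.907 RPKM) and Cd200 (from 3.37 to 15.5 RPKM). Memory and self-renewal genes had 13 of 20 members lower and 3 higher (adjusted p = 0.00175, but adjusted p = 0.119 with an estimated correlation). The Tcf7 relative Lef1 went from 56.1 to 22.5 RPKM. Il7r was at 41.1 ± 1.98 RPKM in acute and 42.9 ± 1.18 RPKM in chronic libraries (limma, adjusted p = 0.397).

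All 23 sterol and fatty acid synthesis genes rose (camera, adjusted p = 2.45e-20, and adjusted p = 0.00405 with an estimated correlation). The mevalonate pathway genes Fdps (from 9.60 to 30.7 RPKM) and Hmgcs1 (from 1.46 to 5.76 RPKM) were examples. Of 12 cytosolic heat shock genes 7 rose and none fell (adjusted p = 0.000456, and adjusted p = 0.0279 with an estimated correlation), including Hsph1 (from 19.6 to 53.9 RPKM) and Hspb1 (from 4.57 to 20.4 RPKM). Endoplasmic reticulum stress genes had 14 of 19 members higher and 4 lower (adjusted p = 3.05e-07, but adjusted p = 0.119 with an estimated correlation), such as the chaperone gene Calr (from 204 to 691 RPKM) and Sdf2l1 (from 23.7 to 104 RPKM). The ATF4 and amino acid response list fell, with 23 of 25 members lower and 1 higher (adjusted p = 5.46e-08, and adjusted p = 0.0282 with an estimated correlation). Besides Trib3, the stress factor gene Ddit3 (CHOP) fell from 723 ± 86.6 to 179 ± 4.47 RPKM. Hypoxia targets had 13 of 21 members lower and 1 higher (adjusted p = 0.00424, but adjusted p = 0.392 with an estimated correlation). They included the angiogenic factor gene Vegfa (from 33.9 to 15.1 RPKM) and Ankrd37 (from 12.4 to 4.68 RPKM). The cell cycle list had 16 of 29 members higher and 7 lower (adjusted p = 0.00208, but adjusted p = 0.119 with an estimated correlation). The replication genes Cdc6 (from 3.77 to 8.84 RPKM) and Rrm2 (from 57.4 to 115 RPKM) were higher. Mki67 was at 52.999 ± 8.05 RPKM in acute and 45.8 ± 4.75 RPKM in chronic libraries (limma, adjusted p = 0.0522, but adjusted p = 0.00179 without OT-I acute library 2).

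The remaining lists did not pass in OT-I cells, namely the respiratory chain (75 genes, 15 higher and 14 lower, adjusted p = 0.345), TCA cycle (adjusted p = 0.439), mitochondrial biogenesis (adjusted p = 0.781), glycolysis (adjusted p = 0.345), NRF2 (adjusted p = 0.414), metallothionein (adjusted p = 0.714), interferon-stimulated (adjusted p = 0.476) and p53 lists (adjusted p = 0.18). Single members that rose included the thioredoxin gene Txn1 (from 216 to 504 RPKM), the oxidative stress-induced gene Osgin1 (from 20.02 to 51.7 RPKM), the zinc importer gene Slc39a10 (from 3.84 to 10.1 RPKM), Ifit2 (from 147 to 445 RPKM) and the interferon-induced GTPase gene Gbp2 (from 316 to 1081 RPKM). The mitochondrial coactivator gene Ppargc1a (from 5.34 to 2.48 RPKM, but adjusted p = 0.0683 with a pseudocount of 0.1), Pink1 (from 44.3 to 26.9 RPKM) and the pro-apoptotic gene Bbc3 (from 32.9 to 16.2 RPKM) fell. Slc2a1 was at 49.5 ± 2.25 RPKM in acute and 46.96 ± 1.73 RPKM in chronic libraries (limma, adjusted p = 0.349), and Nqo1 at 2.76 ± 0.827 and 1.72 ± 0.0385 RPKM. Outside the lists, the interferon-γ-induced chemokine gene Cxcl9 (from 3.73 to 448 RPKM), Ubd, which encodes a ubiquitin-like protein (from 3.18 to 123 RPKM), had large rises. So did the granzyme inhibitor family gene Serpinb9b (from 3.35 to 126 RPKM) and the immunoglobulin joining chain gene Jchain (from 7.55 to 211 RPKM). Cox6a2 (from 29.4 to 0.954 RPKM), Angptl6 (from 36.5 to 1.52 RPKM), Ifit1bl1 (from 15.5 to 1.30 RPKM), Akr1b7 (from 12.1 to 0.860 RPKM) and Cyb5r1 (from 152 to 23.3 RPKM) had the largest falls.

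Melanoma RNA differed between these groups. Of 12 melanocyte genes 8 fell, including Pmel (from 2013 ± 79.9 to 679.5 ± 20.99 RPKM), Tyr (from 78.3 ± 3.82 to 21.2 ± 0.528 RPKM) and Dct (from 1520.0 ± 63.9 to 834 ± 14.4 RPKM), and the other 4 (Mlana, Sox10, Gpnmb and Mc1r) did not pass, although Sox10 was called higher with the replicate block (adjusted p = 0.0164). Genes at least 10 times higher in an OT-I group than in every group without tumour cells numbered 414, and 272 of them changed, 81 higher and 191 lower. Cxcl9, Ubd, Angptl6, Trib3 and Ddit3 were among them, and 7123 of the other genes changed. The rule can also take genes induced in OT-I cells, although its genes are called tumour-enriched below. Genes that both cell types express stay among the other genes, so the 7123 are not changes of OT-I cells alone. B cell markers rose in 6 of 7 cases from low levels, such as Cd79b (from 3.56 ± 0.842 to 15.3 ± 1.09 RPKM). All 3 NK markers rose, such as Klrb1c (from 1.47 ± 0.450 to 6.15 ± 0.370 RPKM). The myeloid markers Mpeg1 (from 1.96 ± 0.123 to 15.6 ± 0.919 RPKM) and Cd14 rose with the other 3 not passing. The CD8 T cell markers had 5 of 7 members lower and 1 higher, with Cd8a going from 106 ± 3.44 to 98.3 ± 2.97 RPKM, a fall not called with rescaled libraries (adjusted p = 0.662) or in 3 other alternatives. Of CD4 T cell markers 1 rose and 2 fell, with Cd4 at 0.603 ± 0.0830 RPKM in chronic libraries, and Alas2 did not pass. Adjusted over the list alone, the gene list counts differed in the respiratory chain (11 higher, 12 lower), mitochondrial biogenesis (2 higher, 7 lower), hypoxia (2 higher, 15 lower), NRF2 (10 higher, 10 lower), ATF4 (2 higher, 23 lower) and cell cycle lists (17 higher, 9 lower). Among lists that did not pass, the median was negative while the test leaned up for the TCA, NRF2, metallothionein and interferon-stimulated lists, and the respiratory chain had a positive median and a negative mean.

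**Figure D2:**
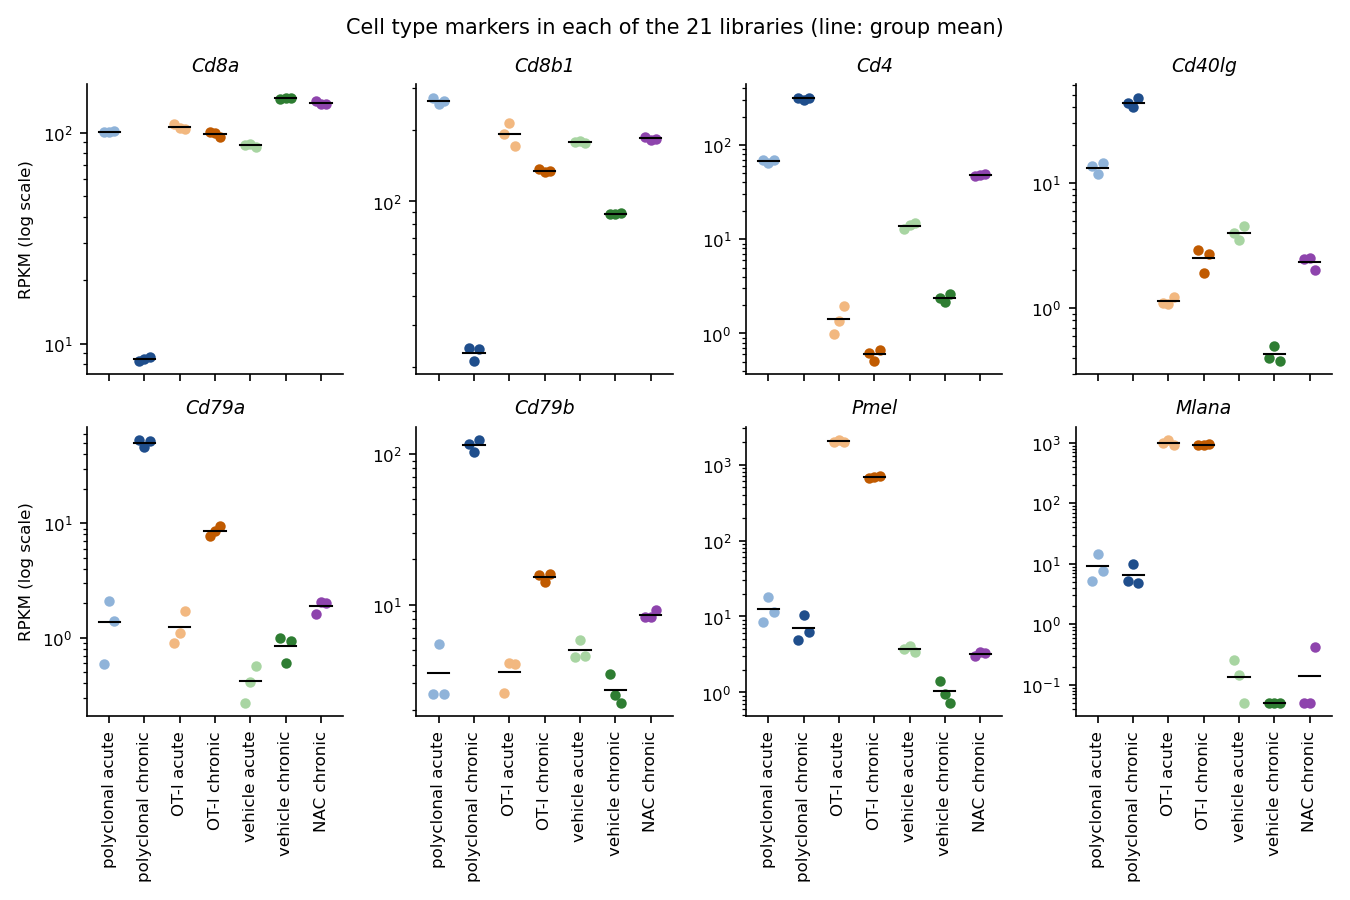
RPKM on a log axis of cell type markers in each library of the 7 groups, with bars at group means and values under 0.05 RPKM drawn at 0.05. Cd8a averaged 8.48 ± 0.165 RPKM in polyclonal chronic libraries and 145 ± 1.37 RPKM in vehicle chronic libraries.

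The vehicle groups asked the same question of repeated stimulation in the experiment that also held NAC. Inhibitory receptor RNA rose sharply, with Lag3 going from 8.94 ± 0.349 to 353 ± 4.35 RPKM (log2 change 5.15, SE 0.064, adjusted p = 1.32e-22). Pdcd1 rose from 8.18 ± 0.627 to 211 ± 3.58 RPKM (log2 change 4.53, SE 0.076) and Havcr2 from 25.2 ± 1.14 to 202 ± 2.62 RPKM (log2 change 2.96, SE 0.046). Tcf7 fell from 176 ± 17.1 to 3.502 ± 0.354 RPKM (log2 change -5.29, SE 0.067). Every cell cycle gene on the list fell, and interferon-stimulated genes were lower. In all, 7433 genes changed, 3093 higher and 4340 lower (limma, adjusted p under 0.05), of which 745 rose and 595 fell at least 2-fold. Rescaled libraries gave 3505 higher and 3789 lower.

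Cytokines, chemokines and cytotoxic molecules had 16 of 20 members higher and 3 lower in vehicle chronic cells (camera, adjusted p = 3.31e-11, and adjusted p = 0.00123 with an estimated correlation). Ifng rose from 4.67 ± 0.538 to 430.5 ± 9.20 RPKM, Gzmb from 5239 ± 531 to 13698 ± 208 RPKM and Ccl3 from 1.91 ± 0.244 to 964 ± 22.96 RPKM. Gzmd (from 17.3 to 2900.5 RPKM), Gzmf (from 2.12 to 1285 RPKM) and Gzmg (from 2.83 to 1628 RPKM) also rose, but these granzyme genes are near-identical copies and the division of reads among them is uncertain. Gzmk, a granzyme gene of less differentiated effector cells, fell from 40.5 to 1.33 RPKM. Of 20 TCR-induced genes 18 rose and none fell (adjusted p = 9.08e-14, and adjusted p = 0.00123 with an estimated correlation). Examples were Rgs16 (from 5.89 to 259 RPKM) and Egr2, an early response factor gene of anergic cells (from 0.879 to 49.96 RPKM). Transcription factors of chronic stimulation had 9 of 14 members higher and 2 lower (adjusted p = 2.25e-06, and adjusted p = 0.00123 with an estimated correlation). The NR4A factor genes Nr4a1 (from 1.15 ± 0.0228 to 40.2 ± 1.26 RPKM) and Nr4a2 (from 1.31 ± 0.0930 to 62.4 ± 0.974 RPKM) were higher. Tox was at 1.06 ± 0.191 RPKM in acute and 0.783 ± 0.220 RPKM in chronic cells (limma, adjusted p = 0.210). Inhibitory receptors had 8 of 15 members higher and 3 lower (adjusted p = 0.000186, and adjusted p = 0.00911 with an estimated correlation). Memory and self-renewal genes had 13 of 20 members lower and 5 higher (adjusted p = 0.00406, but adjusted p = 0.174 with an estimated correlation). With Tcf7, the inhibitor of differentiation gene Id3 fell from 39.5 to 0.863 RPKM, whereas Il7r rose from 78.8 to 152 RPKM.

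All 29 cell cycle genes fell (camera, adjusted p = 1.79e-16, and adjusted p = 0.00123 with an estimated correlation). They included the topoisomerase gene Top2a (from 309 ± 6.93 to 113 ± 0.941 RPKM), Ccnb2 (from 155 to 54.3 RPKM) and Mki67 (from 169 ± 9.88 to 77.5 ± 0.974 RPKM). Interferon-stimulated genes had 18 of 24 members lower and none higher (adjusted p = 5.24e-07, and adjusted p = 0.0296 with an estimated correlation), such as the oligoadenylate synthetase gene Oas3 (from 38.8 to 5.98 RPKM) and Ifit3 (from 5.52 to 0.277 RPKM). The nuclear-encoded respiratory chain and ATP synthase list had 50 of 75 members lower and 3 higher (adjusted p = 0.000815, but adjusted p = 0.573 with an estimated correlation). The subunit genes Ndufa4 (from 323 ± 7.09 to 163 ± 5.16 RPKM) and Ndufb2 (from 89.9 ± 1.88 to 46.9 ± 1.33 RPKM) changed the most. Of 19 TCA cycle genes 10 fell and none rose (adjusted p = 0.0173, but adjusted p = 0.39 with an estimated correlation), including Idh2 (from 21.6 to 7.31 RPKM) and Suclg2 (from 6.63 to 2.92 RPKM). NRF2 and antioxidant genes had 16 of 24 members lower and 4 higher (adjusted p = 0.025, but adjusted p = 0.366 with an estimated correlation). The glutathione synthesis gene Gclm went from 29.3 to 9.75 RPKM and the peroxiredoxin gene Prdx1 from 187 to 73.1 RPKM. The p53 targets had 9 of 14 members lower and 2 higher (adjusted p = 0.0336, but adjusted p = 0.229 with an estimated correlation), with Trp53inp1 falling from 80.6 to 21.98 RPKM and Perp rising from 4.38 to 18.96 RPKM.

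ATF4 and amino acid response genes had 12 of 25 members higher and 6 lower in vehicle chronic cells (camera, adjusted p = 0.0335, but adjusted p = 0.39 with an estimated correlation). Cth (from 0.263 ± 0.196 to 12.05 ± 0.657 RPKM) and Atf3 (from 2.93 ± 0.212 to 19.2 ± 0.217 RPKM) were higher. Endoplasmic reticulum stress genes had 12 of 19 members higher and 4 lower (adjusted p = 0.0281, but adjusted p = 0.472 with an estimated correlation), such as the chaperone gene Hspa5 (from 304 to 469 RPKM). Sterol and fatty acid synthesis genes had 14 of 23 members higher and 3 lower (adjusted p = 0.000404, but adjusted p = 0.215 with an estimated correlation), Scd1 among them (from 11.6 to 47.3 RPKM). Mitochondrial biogenesis (adjusted p = 0.135), glycolysis (adjusted p = 0.122), hypoxia (adjusted p = 0.215), heat shock (adjusted p = 0.736) and metallothionein lists (adjusted p = 0.354) did not pass. Within them, the mitochondrial transcription factor gene Tfam (from 20.4 to 12.2 RPKM), Pdk1 (from 42.5 to 12.1 RPKM), the mitophagy receptor gene Bnip3 (from 71.6 to 25.2 RPKM) and Slc2a1 (from 69.1 to 52.2 RPKM) fell, while the glucose transporter gene Slc2a3 rose from 39.3 to 109 RPKM. Nqo1 fell from 2.35 to 0.830 RPKM. Outside the lists, the proenkephalin gene Penk (from 0.703 to 1069.9 RPKM) and Serpinb9b (from 2.19 to 833 RPKM) rose the most, and Igfbp4 (from 88.3 to 0.753 RPKM), the chemokine receptor gene Cxcr3 (from 109.8 to 1.74 RPKM) and Ifit1bl1 (from 17.3 to 0.218 RPKM) were among the largest falls.

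Cell type markers moved with these groups. Of the CD8 T cell markers 4 rose and 2 fell, with Cd8a going from 87.1 ± 1.76 to 145 ± 1.37 RPKM and Cd8b1 from 179 ± 1.16 to 88.8 ± 0.253 RPKM. Cd4 fell from 13.9 ± 0.888 to 2.39 ± 0.236 RPKM, Cd40lg fell and Foxp3 rose from a low level. Among B cell markers Cd79b fell from 4.96 to 2.73 RPKM and the other 6 did not pass. The myeloid markers Itgam, Cd14 and Itgax (from 2.53 to 7.52 RPKM) rose, and the NK receptor gene Klra7, which has close copies, rose from 18.2 to 152 RPKM. Of melanocyte genes 3 fell, and Alas2 did not pass. Adjusted over the list alone, the gene list counts differed only in the transcription factors (10 higher, 2 lower), glycolysis (3 higher, 12 lower) and p53 targets (3 higher, 9 lower). The heat shock list had a negative median and a positive mean.

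The comparison of NAC with vehicle asked what the antioxidant changed in chronically stimulated cells. Memory-associated RNA was higher with NAC, with Tcf7 rising from 3.502 ± 0.354 to 116 ± 2.58 RPKM (log2 change 4.70, SE 0.067, adjusted p = 1.36e-20) and the lymph node homing receptor gene Ccr7 rising from 29.6 ± 1.22 to 416 ± 2.99 RPKM (log2 change 3.77, SE 0.084). Effector RNA was lower, with Gzmb falling from 13698 ± 208 to 1903 ± 28.1 RPKM (log2 change -2.85, SE 0.11) and Ifng falling from 430.5 ± 9.20 to 118 ± 3.91 RPKM (log2 change -1.86, SE 0.079). Havcr2 fell from 202 ± 2.62 to 28.7 ± 0.520 RPKM, while Pdcd1 fell less, from 211 ± 3.58 to 129.9 ± 4.92 RPKM, and Tox rose from 0.783 ± 0.220 to 19.1 ± 0.348 RPKM. Metallothionein and ATF4 response genes were lower. In all, 7716 genes changed, 4862 higher and 2854 lower (limma, adjusted p under 0.05), of which 741 rose and 432 fell at least 2-fold. With each library rescaled to the same median, the split was 3817 higher and 3512 lower.

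Memory and self-renewal genes had 18 of 20 members higher and 1 lower with NAC (camera, adjusted p = 1.88e-08, and adjusted p = 0.00939 with an estimated correlation). The member that fell was Il7r (from 152 to 126 RPKM). Cytokines, chemokines and cytotoxic molecules had 17 of 20 members lower and 1 higher (adjusted p = 9.43e-12, and adjusted p = 0.00307 with an estimated correlation). Ccl3 (from 964 ± 22.96 to 79.7 ± 4.34 RPKM) and Il10 (from 41.8 ± 0.324 to 1.59 ± 0.345 RPKM) were lower. Inhibitory receptors had 11 of 15 members lower and 4 higher (adjusted p = 0.00563, but adjusted p = 0.0648 with an estimated correlation). The receptor gene Cd244 went from 49.7 to 11.1 RPKM and Lag3 from 353 to 281 RPKM. TCR-induced genes had 12 of 20 members lower and 3 higher (adjusted p = 0.000782, but adjusted p = 0.0845 with an estimated correlation). Tnfrsf9, which encodes the costimulatory receptor 4-1BB, fell from 905 to 361 RPKM, and the interleukin 2 receptor gene Il2ra fell from 346 to 112 RPKM. The transcription factors of chronic stimulation did not pass (7 of 14 higher, 6 lower, adjusted p = 0.615), with Id2 falling from 714 ± 19.4 to 178 ± 4.82 RPKM beside the rise of Tox. Interferon-stimulated genes had 20 of 24 members higher and 1 lower (adjusted p = 7.09e-05, but adjusted p = 0.0845 with an estimated correlation), Ifit2 among them (from 5.64 to 14.3 RPKM).

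All 5 metallothionein and zinc genes fell with NAC (camera, adjusted p = 0.00033, and adjusted p = 0.00939 with an estimated correlation). Largest were the falls of the metal-binding protein genes Mt2 (from 209.6 ± 10.8 to 3.53 ± 0.927 RPKM) and Mt1 (from 323 ± 16.4 to 16.4 ± 0.707 RPKM). ATF4 and amino acid response genes had 21 of 25 members lower and none higher (adjusted p = 9.43e-12, and adjusted p = 0.00939 with an estimated correlation). The amino acid transporter gene Slc7a5 (from 137 ± 3.88 to 25.7 ± 1.58 RPKM) and Cth (from 12.05 ± 0.657 to 0.984 ± 0.289 RPKM) fell. Endoplasmic reticulum stress genes had 13 of 19 members lower and 2 higher (adjusted p = 8.08e-06, but adjusted p = 0.178 with an estimated correlation), with Calr going from 604 to 238 RPKM and Sdf2l1 going from 94.1 to 30.6 RPKM. NRF2 and antioxidant genes had 15 of 24 members lower and 5 higher (adjusted p = 8.81e-05, but adjusted p = 0.0845 with an estimated correlation), including the sulfiredoxin gene Srxn1 (from 24.00 to 5.00 RPKM) and Hmox1 (from 12.5 to 3.24 RPKM). Nqo1 was at 0.830 ± 0.116 RPKM with vehicle and 0.616 ± 0.0748 RPKM with NAC (limma, adjusted p = 0.599). Glycolysis genes had 15 of 19 members lower and 3 higher (adjusted p = 1.10e-05, but adjusted p = 0.24 with an estimated correlation). Hk2 (from 18.9 ± 0.447 to 3.41 ± 0.315 RPKM) and Slc2a1 (from 52.2 ± 1.36 to 17.8 ± 1.03 RPKM) changed the most. Hypoxia targets had 14 of 21 members lower and 6 higher (adjusted p = 0.00446, but adjusted p = 0.398 with an estimated correlation). Its members moved both ways, with Bnip3 falling from 25.2 to 8.16 RPKM and Selenbp1 rising from 0.476 to 4.39 RPKM. The respiratory chain list had 18 of 75 members lower and 7 higher (adjusted p = 0.0442, but adjusted p = 0.702 with an estimated correlation), with Uqcrq going from 98.4 to 53.6 RPKM and Ndufa6 rising from 137 to 213 RPKM.

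Lists of the TCA cycle (adjusted p = 0.181), mitochondrial biogenesis (adjusted p = 0.876), heat shock (adjusted p = 0.615), cell cycle (14 of 29 higher, 7 lower, adjusted p = 0.224), sterol synthesis (adjusted p = 0.113) and p53 targets (adjusted p = 0.307) did not pass. Within them Idh2 (from 7.31 to 15.3 RPKM), Pink1 (from 18.5 to 50.7 RPKM), Hspa1a (from 4.02 to 17.4 RPKM), the mitotic kinesin gene Kif11 (from 44.1 to 72.99 RPKM), Mki67 (from 77.5 to 112 RPKM), Trp53inp1 (from 21.98 to 88.5 RPKM) and the death receptor gene Fas (from 5.70 to 22.7 RPKM) rose. Outside the lists, the largest rises included Pou2af1, a coactivator gene of B and follicular helper T cells (from 0.865 to 30.2 RPKM), Arl5c (from 4.33 to 84.01 RPKM), the interferon-inducible GTPase gene Iigp1 (from 1.253 to 32.8 RPKM), the glutathione transferase gene Gsta4 (from 0.291 to 18.2 RPKM) and Tspan32 (from 3.53 to 65.8 RPKM). The largest falls included Gzmg (from 1628 to 37.7 RPKM), Il13 (from 201 to 4.16 RPKM), the activin subunit gene Inhba (from 51.5 to 1.19 RPKM) and Gpx8, a glutathione peroxidase family gene (from 26.8 to 0.509 RPKM). Among markers, Cd8a was at 145 ± 1.37 RPKM with vehicle and 138 ± 2.42 RPKM with NAC (limma, adjusted p = 0.115, but adjusted p = 0.0139 with rescaled libraries). Of the 7 genes of the CD8 T cell list 4 rose. They were Cd8b1 (from 88.8 ± 0.253 to 184 ± 2.75 RPKM) and Cd3e, Cd2 and Cd5, which CD4 T cells express too. All 4 CD4 and regulatory T cell markers rose, with Cd4 going from 2.39 ± 0.236 to 47.9 ± 1.12 RPKM and Foxp3 from 0.663 ± 0.0778 to 3.12 ± 0.182 RPKM. B cell markers rose for Cd79a and Cd79b (from 2.73 to 8.57 RPKM) and the other 5 did not pass. The myeloid markers Itgam and Itgax (from 7.52 ± 0.378 to 26.4 ± 0.749 RPKM) rose and Cd14 fell, 2 NK markers fell, 4 melanocyte genes rose, and Alas2 did not pass. Adjusted over the list alone, the counts differed in the respiratory chain (7 higher, 17 lower), mitochondrial biogenesis (4 higher, 3 lower) and p53 target lists (5 higher, 7 lower). For the transcription factor list the median was positive and the test leaned down, and the p53 list had a negative median and a positive mean.

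**Figure D3:**
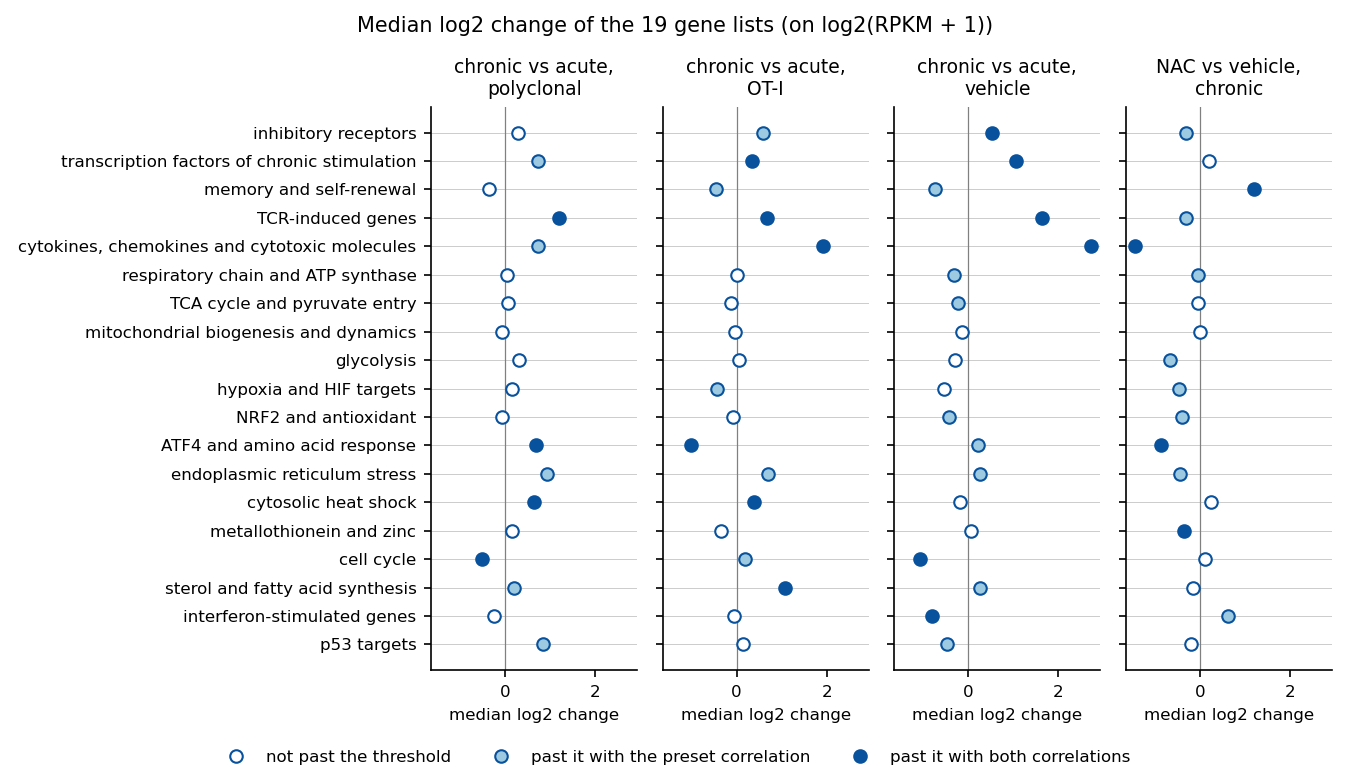
Median log2 change of each of the 19 gene lists in the chronic against acute and NAC against vehicle comparisons. The ATF4 and amino acid response list had a median of 0.68 in polyclonal, -1.01 in OT-I and 0.22 in vehicle cells, and of -0.85 with NAC.

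NAC chronic cells were also set against vehicle acute cells, to show what still differed from acute cells after the antioxidant. In this comparison 8368 genes changed, 4587 higher and 3781 lower (limma, adjusted p under 0.05), of which 1060 rose and 592 fell at least 2-fold. Rescaling to the same median gave 4161 higher and 4071 lower. Among cell type markers, Cd4 was at 13.9 RPKM in vehicle acute and 47.9 RPKM in NAC chronic cells, and Cd8a at 87.1 and 138 RPKM. Other CD4 and regulatory T cell markers went both ways, with Foxp3 at 0.279 and 3.12 RPKM and Cd40lg at 4.01 and 2.32 RPKM. Penk (from 0.703 ± 0.104 to 649 ± 15.1 RPKM), the calmodulin-binding protein gene Nrgn (from 1.89 ± 0.867 to 392 ± 17.8 RPKM), Serpinb9b (from 2.19 to 349 RPKM) and Gng11 (from 0.355 to 70.3 RPKM) rose the most. Igfbp4 (from 88.3 to 0.840 RPKM), Mt2 (from 201 to 3.53 RPKM), Gzmk (from 40.5 to 0.391 RPKM) and Adam19 (from 36.4 to 0.826 RPKM) fell the most. All 29 cell cycle genes were lower than in acute cells (camera, adjusted p = 9.63e-15, and adjusted p = 0.0038 with an estimated correlation). TCR-induced genes had 15 of 20 members higher and 4 lower (adjusted p = 2.26e-05), transcription factors of chronic stimulation 10 of 14 higher and 3 lower (adjusted p = 0.00136), and NRF2 genes 20 of 24 lower and 2 higher (adjusted p = 5.34e-07). For each of these 3 lists the adjusted p = 0.0426 with an estimated correlation. Memory and self-renewal genes split into 9 higher and 10 lower of 20 and did not pass (adjusted p = 0.869), with a negative median and a positive mean. Inhibitory receptors had 10 of 15 members higher and 3 lower (adjusted p = 0.0114, but adjusted p = 0.0884 with an estimated correlation), and cytokines 12 of 20 higher and 7 lower (adjusted p = 0.013, but adjusted p = 0.198 with an estimated correlation). Sterol synthesis genes had 14 of 23 members higher and 3 lower (adjusted p = 0.0314, but adjusted p = 0.381 with an estimated correlation).

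Lower than in vehicle acute cells were the respiratory chain (50 of 75 lower, 5 higher, adjusted p = 4.33e-06, but adjusted p = 0.384 with an estimated correlation), TCA cycle (13 of 19 lower, 1 higher, adjusted p = 0.000852, but adjusted p = 0.245 with an estimated correlation) and glycolysis lists (15 of 19 lower, 4 higher, adjusted p = 0.000298, but adjusted p = 0.287 with an estimated correlation). The same held for hypoxia targets (15 of 21 lower, 2 higher, adjusted p = 0.000424, but adjusted p = 0.269 with an estimated correlation) and ATF4 genes (18 of 25 lower, 3 higher, adjusted p = 9.96e-05, but adjusted p = 0.115 with an estimated correlation). Endoplasmic reticulum stress genes had 14 of 19 members lower and 4 higher (adjusted p = 0.00619, but adjusted p = 0.37 with an estimated correlation), metallothionein genes 3 of 5 lower and 1 higher (adjusted p = 0.022, but adjusted p = 0.0884 with an estimated correlation), and interferon-stimulated genes 13 of 24 lower and 7 higher (adjusted p = 0.022, but adjusted p = 0.287 with an estimated correlation). Mitochondrial biogenesis (adjusted p = 0.201), heat shock (adjusted p = 0.917) and p53 lists (adjusted p = 0.0746) did not pass, and the heat shock list had a negative median and a positive mean. Adjusted over the list alone, the counts differed in the respiratory chain (5 higher, 51 lower) and sterol lists (14 higher, 5 lower).

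The genes that chronic stimulation moved at least 2-fold in the polyclonal experiment, which shares no library with the NAC comparison, were followed under NAC. In the polyclonal chronic libraries Cd8a was lower and Cd4 and B cell RNA higher, so these lists also hold genes of that shift. The 929 raised genes had a median log2 change of -0.18 with NAC, with 425 lower and 229 higher (429 and 231 adjusted over the list alone). The camera test gave p = 2.24e-08, but p = 0.163 with an estimated correlation. The 724 lowered genes had a median of 0.45, with 460 higher and 131 lower (465 and 134 adjusted over the list alone), and p = 2.81e-07, but p = 0.116 with an estimated correlation. For both lists the exact permutation test over the 10 splits of the 6 libraries gave p = 0.1, two-sided, the smallest that 3 against 3 allows. The 4 lists that follow were added after the data were seen. They rest on OT-I libraries that also held melanoma RNA, so they may hold genes of the tumour cells. Genes raised at least 2-fold in OT-I cells (368) had a median of -0.27 with NAC (camera p = 8.75e-13, and p = 0.0288 with an estimated correlation), and those lowered (352) a median of 0.34 (p = 5.44e-05, but p = 0.28 with an estimated correlation). The genes raised in both experiments (148) had a median of -0.43, with 84 lower and 31 higher (p = 1.64e-12, and p = 0.0418 with an estimated correlation). Of the 87 lowered in both, Tcf7 among them, 72 rose and 6 fell with NAC, with a median of 0.93 (p = 8.20e-15, and p = 0.0129 with an estimated correlation).

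**Figure D4:**
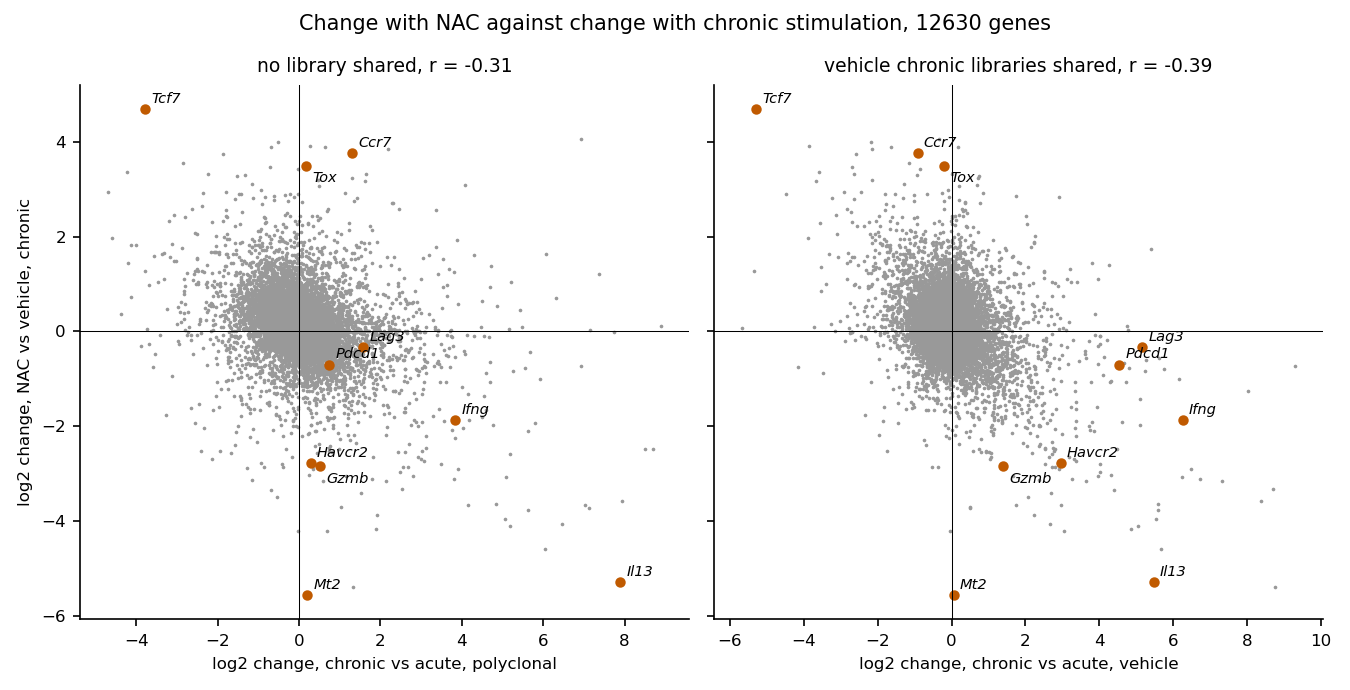
Log2 change of each of the 12630 genes in chronic against acute polyclonal cells (x) and in NAC against vehicle chronic cells (y), with genes named in the text marked. Pearson r across genes was -0.306.

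Across genes, which are not independent replicates, 6 correlations of log2 changes were computed. Pearson r was 0.342 between the polyclonal and OT-I chronic effects, 0.482 between polyclonal and vehicle, and 0.269 between OT-I and vehicle. The rank correlation (Spearman rho) was 0.326, 0.415 and 0.107 for these pairs. The NAC effect had r of -0.306 with the polyclonal and -0.333 with the OT-I chronic effect, pairs that share no library. The pairs of OT-I with vehicle and with NAC were added after the data were seen. Genes raised in both the polyclonal and vehicle experiments numbered 1700 where independent lists would give 884, and those lowered in both 2493 where 1543 would be given. For OT-I and vehicle 957 were raised in both (692 for independent lists) and 1847 lowered in both (1570), while 1075 were higher in OT-I and lower in vehicle chronic cells (971). With the vehicle chronic effect, which shares the vehicle chronic libraries, the NAC effect had r of -0.390, a covariance of -0.189 and 2209 genes lower in chronic cells and higher with NAC (1671 for independent lists). A simulation of unchanged groups on these shared libraries gave r of -0.499 and a covariance of -0.00788, which leaves a difference in covariance of -0.181. Part of this overlap may come from the shared libraries, which are too few to split.

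The chronic effects of the experiments were compared directly. In polyclonal chronic libraries Cd8a fell from 101 to 8.48 RPKM while Cd4 and B cell RNA rose, and OT-I libraries held melanoma RNA. The differences below may therefore hold shifts of cell types as well as responses of CD8 T cells. The OT-I effect differed from the polyclonal effect in 7047 genes, 3365 higher and 3682 lower (limma, adjusted p under 0.05), of which 690 were higher and 1116 lower by at least 2-fold. Cxcl9 (difference in log2 change 6.61, SE 0.21), Eomes (5.43), Klrb1c (5.08) and the innate receptor gene Nod1 (4.72) differed most towards OT-I, and Akr1c18 (-8.70, SE 0.31), Pth (-8.66), Ccl22 (-7.87) and the neuropeptide gene Gal (-7.58) most towards polyclonal cells. Eomes fell in polyclonal chronic cells and rose in OT-I chronic cells. The vehicle effect differed from the polyclonal effect in 6614 genes, 3165 higher and 3449 lower, of which 733 were higher and 829 lower by at least 2-fold. Gzmg (7.44, SE 0.20), the chemokine gene Xcl1 (7.01), Gzmd (6.74) and Gzmf (6.18) differed most towards vehicle, and Ccl22 (-9.03, SE 0.38), Pou2af1 (-7.25), Gal (-7.11) and the transglutaminase gene Tgm2 (-7.02) towards polyclonal cells. The rise of Pdcd1 was larger in vehicle cells by 3.79 on the log2 scale (limma, adjusted p = 1.30e-16), and that of Lag3 by 3.58 (adjusted p = 2.76e-17). Of the 8097 genes that changed in polyclonal cells, 6736 remain when those that changed in opposite directions in the vehicle experiment are left out. This count comes from the main calls and tests nothing further.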

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

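The tests of other cells and of tumour cells, with their thresholds, the count of splits by pairs and the reversed labels were chosen after the results were seen, and the outcomes expected of the other splits were written down only after the split counts were seen. The chronic effect of OT-I cells differed from that of polyclonal cells in 7047 genes by limma's test of the difference. Relative to the polyclonal effect, the log2 change was higher for Cxcl9 (6.61), Eomes (5.43), Klrb1c (5.08), Nod1 (4.72), Ifng (2.51), Havcr2 (1.72), Tcf7 (1.63), Mki67 (1.02), Pdcd1 (0.90) and Gzmb (0.76). It was lower for Akr1c18 (-8.70), Pth (-8.66), Ccl22 (-7.87), Gal (-7.58), Tox (-0.73) and Slc2a1 (-0.48). Of the 95 genes that the naming rule took for either comparison, 82 differed and 18 of these changed in opposite directions, among them Eomes, Cxcr5, Cth, Idh2, Hmox1, Vegfa and Ifit2.

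The vehicle experiment also set chronic against acute stimulation of C57BL/6 cells, and its effect differed from the polyclonal one in 6614 genes. It was higher for Gzmg (7.44), Xcl1 (7.01), Gzmd (6.74), Gzmf (6.18), Pdcd1 (3.79), Lag3 (3.58), Havcr2 (2.67), Ifng (2.42), Il7r (1.04) and Gzmb (0.87), and lower for Ccl22 (-9.03), Pou2af1 (-7.25), Gal (-7.11), Tgm2 (-7.02), Tcf7 (-1.50) and Slc2a1 (-0.80). Of 88 named genes 75 differed, and 7 changed in opposite directions, namely Aldoc, Bnip3, Cxcr5, Idh2, Ndufa4, Slc2a1 and Tomm40.

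In the polyclonal chronic libraries Cd8a and Cd8b1 were lower while Cd4 and B cell markers were higher. A response of CD8 T cells that both anti-CD3 experiments share is argued against as the whole cause, because the log2 change of Cd8a was 4.16 higher in the vehicle than in the polyclonal experiment. Cd8a rose there, although Cd8b1 fell (179 ± 1.16 to 88.8 ± 0.253 RPKM), so part of the fall of Cd8b1 may be shared. A larger share of B cells and CD4 T cells in the chronic culture may account for the pattern: among the abundant B cell transcripts Cd74 (2.97 ± 0.902 to 646 ± 70.3 RPKM), H2-Aa, H2-Ab1 and H2-Eb1, which are outside the marker list, the smallest ratio of chronic to acute was 18.97. The negative selection of CD8 T cells should remove both cell types, and 1 of 8 B cell markers was at 1 RPKM or more in every vehicle acute library. Which of the changed genes come from CD8 T cells, a wrong label of these libraries, and any difference between the mice or cultures of the experiments, stay open and untested.

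Pigment genes of the tumour cells were lower in OT-I chronic libraries. Fewer tumour cells as the only cause is argued against, because it would lower all markers of these cells alike. Of the 12 melanocyte markers 7 lay over 0.5 and over 3 SE from their median log2 change, from Trpm1 (-2.24, SE 0.20) to Sox10 (0.20, SE 0.13). A smaller share of tumour RNA together with a response of those cells to T cell cytokines may still contribute, and was not tested apart. Whether the fall of the ATF4 list comes from the tumour cells cannot be told apart from a fall in OT-I cells, since the libraries mix both and 4 of the 25 members (Ddit3, Trib3, Nupr1 and Aldh1l2) were at least 10 times higher in an OT-I group than in every group without tumour cells.

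Other splits of the libraries tested whether regrouping them by chance gives as many calls. For the difference between OT-I and polyclonal effects 1 of 100 splits, the real one, reached 7047 genes and the highest other gave 5546. For the difference between vehicle and polyclonal effects 1 of 100, the real one, reached 6614 and the highest other gave 5481. Because the numbers may pair the polyclonal libraries, the 40 splits that part these 3 pairs were also counted. Of these the real one again gave the most, with 5546 and 5331 as the highest others. Regrouping the libraries of an experiment also removes its own chronic effect, so these counts cannot show whether the effects of the experiments differ. They do not exclude a technical spread between libraries either. Reversing the labels of 1 experiment, which tests the sum of the effects and is not among the splits, gave 8643 and 8473 genes. The high counts of other splits came from splits that kept the real groups of 1 experiment. The comparisons of 3 against 3 have 10 splits each, too few for a share under 0.05. Their real counts and highest others were 8097 and 1641 for polyclonal, 7395 and 4 for OT-I, 7433 and 0 for vehicle, 7716 and 0 for NAC, and 8368 and 0 for NAC chronic against vehicle acute. Of the polyclonal splits, 4 part all 3 pairs of same-numbered libraries, and the other 3 of these gave 0 genes, while those that keep a pair gave up to 1641.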

How the results depend on the processing

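A fit without doubted libraries, counts that left doubted genes out of the main calls, and limma's voom were chosen after the results were seen. Leaving genes out of the main calls was no new fit. The counts of changed genes stayed within 1.5 times of the main value under every alternative except the 2-fold threshold, which left 1653 polyclonal, 720 OT-I, 1340 vehicle, 1173 NAC and 1652 NAC chronic against vehicle acute genes, and 1806 and 1562 genes for the OT-I and vehicle differences from polyclonal. Fewer genes follow from the threshold itself. Lists passing fell from 9 to 4 in polyclonal, 11 to 6 in OT-I, 14 to 6 in vehicle, 12 to 4 in NAC and 15 to 4 in NAC chronic against vehicle acute cells with an estimated correlation, and fry called 17 in polyclonal cells. Fry asks another question of each list, and the cause of the other losses was not tested.

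Leaving out 1 library at a time gave 7566 to 8407 genes for polyclonal, 6648 to 7175 for OT-I, 6857 to 6977 for vehicle, 7118 to 7166 for NAC and 7862 to 8052 for NAC chronic against vehicle acute, and 6590 to 7394 and 6145 to 6946 for the differences. Lists passing were 9 to 11, 10 to 12, 14 to 14, 11 to 12 and 14 to 16. Median changes under NAC were -0.20 to -0.15 for polyclonal raised and 0.44 to 0.46 for lowered genes. Without the 3 libraries with raised low genes, 8815, 8446, 8585, 8768 and 9303 genes changed, and 8231 and 7752 differed. Voom on the recovered reads called 7649, 8472, 7832, 7954 and 8659, and 6851 and 6267. With only the compared groups in the fit, 6748 polyclonal, 7191 OT-I, 8689 vehicle, 9146 NAC and 9471 NAC chronic against vehicle acute genes changed. The differences then numbered 5997 and 6306.

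With the replicate block the counts were 8661 for polyclonal, 7947 for OT-I, 7745 for vehicle, 8006 for NAC and 8656 for NAC chronic against vehicle acute, and 7480 and 7007 for the differences. The median changes under NAC (-0.18 and 0.45) and the correlations across genes are unaltered by the block. Among lists, the block took inhibitory receptors in OT-I cells from adjusted p = 0.0478 to 0.0513 and changed no other call. Outside the polyclonal experiment correlations of same-numbered libraries ran from -0.167 in OT-I cells to 0.0790 between vehicle acute and NAC chronic cells. Between those last groups all 3 pairs matched their own number best, but at these low values. For named genes and single lists, 4461 alternatives left the call as it was, 51 lost it and 47 gained it, and none reversed a direction. Of those that left it, 46 came from leaving out tumour-enriched genes and 53 from leaving out discordant genes. Neither was a new fit, so these could not change a call. The filters, the replicate block and the fit of only the compared groups leave the log2 change of a gene as it is. For genes, these alternatives therefore could not reverse a direction. Most losses (37) came with the estimated correlation and most gains (25) with fry. Inhibitory receptors in OT-I cells also lost their call with a pseudocount of 0.1 (adjusted p = 0.0693), the stricter filter (0.0832) and rescaled libraries (0.104). The fall of Cd8a in OT-I cells lost its call when libraries were rescaled (limma, adjusted p = 0.662) and when only the compared groups were fitted (0.121). It also lost it without OT-I acute library 1 or chronic library 3. Ppargc1a in OT-I cells lost its call with a pseudocount of 0.1.

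Calls were gained by Sox10 in OT-I chronic libraries under 5 alternatives, among them rescaled libraries (limma, adjusted p = 0.0262) and voom (9.69e-05). Mki67 in OT-I cells gained one under 4, with voom (0.0382), the stricter filter (0.0479) and without OT-I acute library 2 or chronic library 1 (0.00179 and 0.0238). Cd8a with NAC gained one with rescaled libraries (0.0139) and with only the compared groups (0.0140), where Nqo1 also did (0.0290). Without the libraries with raised low genes Tox was called higher in polyclonal (0.00604) and lower in vehicle chronic cells (0.0472), and Alas2 lower in polyclonal cells (0.00360). Il4 was called higher in vehicle chronic cells without vehicle acute library 2 (0.0206). Among lists, inhibitory receptors in polyclonal cells passed with a pseudocount of 0.1 and with no filter (adjusted p = 0.0424 in each). Under the stricter filter the respiratory chain with NAC (0.0532) and, in NAC chronic against vehicle acute cells, metallothionein genes (0.0586) lost theirs, and sterol genes lost theirs there with rescaled libraries (0.0905) and without the libraries with raised low genes (0.0527).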

Other observations

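The tests about NAC, with their thresholds, were chosen after the result was seen, and so were the genes below that the naming rule did not take. In polyclonal chronic libraries, where Cd4 rose from 67.5 to 312 RPKM and Cd8a fell from 101 to 8.48 RPKM, the type 2 cytokine genes Il4 and Il5 and the factor gene Gata3 were higher. Il4 rose from 1.36 ± 0.590 to 118 ± 13.1 RPKM (log2 change 5.69, limma adjusted p = 3.75e-15), Il5 from 2.06 ± 0.965 to 383 ± 23.6 RPKM (log2 change 7.02, adjusted p = 4.32e-17) and Gata3 from 34.4 ± 0.533 to 121 ± 3.46 RPKM (adjusted p = 1.83e-17). In vehicle chronic cells Il5 reached 23.8 ± 2.11 RPKM and Il13 201 ± 13.7 RPKM, and with NAC they were at 0.967 ± 0.292 and 4.16 ± 0.365 RPKM. Il4 was at 1.23 ± 0.750 RPKM in vehicle acute and 1.70 ± 0.0620 RPKM in vehicle chronic cells. In OT-I libraries, Gata3 fell from 8.47 ± 0.501 to 5.02 ± 0.379 RPKM (log2 change -0.65, adjusted p = 4.94e-10), and the class II genes Cd74 (316 ± 8.37 to 700.1 ± 16.2 RPKM) and H2-Aa (64.2 ± 5.28 to 188 ± 7.86 RPKM) rose. With NAC, Nr4a1 (40.2 ± 1.26 to 108 ± 5.41 RPKM), Nr4a3 (34.7 ± 0.711 to 75.5 ± 0.417 RPKM) and Irf4 (36.2 ± 0.881 to 55.5 ± 0.461 RPKM) rose.

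Cytokine and granzyme transcripts were lower and Tcf7 and Cd4 higher with NAC. Dilution of the CD8 T cells by other cells is argued against for the lower transcripts by the log2 change of Cd8a, -0.068 (SE 0.036), or -0.17 with rescaled libraries, where genes lowered at least 2-fold had a median of -1.45. For the higher Cd4 a small share of other T cells may contribute, since the 3 other CD4 and regulatory T cell markers rose, Foxp3 and Cd40lg among them. Negative selection of CD8 T cells should remove such cells. Whether they also add to Tcf7 was not tested, and polyclonal chronic libraries had Cd4 at 312 RPKM but Tcf7 at 2.59 RPKM. A weaker TCR stimulus cannot be told apart from another effect of NAC: the TCR-induced list had 12 of 20 members lower and 3 higher (camera, adjusted p = 0.000782, but adjusted p = 0.0845 with an estimated correlation), while its median over vehicle acute cells was 92.2% of that without NAC. Single genes went the other way. Outside that list Nr4a1, Nr4a3 and Irf4, chosen after the result was seen, rose with NAC. Within it Egr2 was at 49.96 ± 0.724 RPKM in vehicle chronic and 54.6 ± 1.80 RPKM in NAC chronic cells. Whether NAC acts on the cytokine, granzyme, Tcf7 and Cd4 transcripts with or without repeated stimulation cannot be told apart either, as 0 libraries held acute cells with NAC.

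Some values belong to no comparison. Polyclonal libraries held 170 to 235 reads of Tyrp1 and 90 to 132 of Dct each, against 76503 to 150270 and 41487 to 82284 in OT-I libraries, and the vehicle and NAC libraries 0 of Tyrp1 and 0 to 1 of Dct. Reads of 4 Y-linked genes numbered 1945 to 3691 per OT-I library, 0 in the polyclonal libraries and 0 to 4 in the vehicle and NAC libraries. In polyclonal acute library 2, polyclonal chronic library 2 and OT-I acute library 3, 170, 416 and 150 genes were under 0.5 RPKM, where the other libraries had 1027 to 2267. Rn45s, a ribosomal precursor, took 2.65% of reads in OT-I chronic library 3 and 0.0902% in vehicle acute library 1.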
